A study of Mus musculus with 6 samples.

How the data were processed

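LT-HSCs sorted as Lin-Sca1+CD150+CD48- cells from the bone marrow of 8-week-old mice were profiled on 6 arrays, 3 from dKO mice (MxCre with floxed c-myc and N-myc) and 3 from control mice with the floxed genes alone. Per the labels, all mice received 2 daily pI-pC doses, each array held a pool of 3 dKO or 2 control mice, and RNA was extracted with Trizol and amplified over 2 rounds with the NuGEN WT-Ovation Pico kit, made for very small RNA amounts, before biotin labelling. Amplification of this kind can compress or distort differences between transcripts. The platform, per the annotation table used here, was a whole-genome mouse array of 45101 probe sets, 64 of them array controls.

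The deposited values are RMA expression values on a log2 scale, per the submitters' processing notes, which name RMA and no version. As usually run, RMA subtracts background, normalizes the arrays to each other and summarizes the probes of a set; its settings are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 1.49 to 13.80, and array medians lay between 5.90 and 5.97. Because the arrays were scaled to each other, a change in total RNA per cell cannot be seen, and all changes are relative. RMA background handling also compresses changes of dim probe sets.

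Groups and replicate numbers were taken from the sample titles. Replicate numbers are shared by the groups, but nothing in the labels ties equal numbers to a shared day or litter, so no block was used. All value columns mapped to a sample, and no scan date or other batch was given in the sources used here. Each array is a separate pool of mice, so p-values of single probe sets measure the spread between pools. Those of gene lists at a preset correlation, described below, compare the genes of a list with other genes. They do not measure that spread alone.

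Probe sets were named through a platform annotation table: 34945 of the 45037 non-control probe sets had 1 gene symbol, 932 several and 9160 none. Probe sets with several symbols or none were tested but never named. Entrez identifiers of 34741 single-gene probe sets were in the RefSeq gene table used for symbols (assembly GRCm38.p6), and 0 symbols changed. No coordinates are given because the sources used here name no genome build for the array's probe sets. Among 18193 genes, 9010 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all 6 arrays. Of 484 genes with 2 or more called probe sets, 3 had calls in both directions.

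Each non-control probe set was fitted with limma's lmFit and eBayes at default settings (limma 3.58.1, R 4.3.3), dKO minus control, with 4 residual and 3.19 prior degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over 45037 probe sets with a threshold of 0.05. Standard errors (SE) are from limma, and SD is over the 3 arrays of a group. Where 1 group's mean lay in the negative control range, the fold given as a lower bound is the other group's mean less the highest negative control value, 3.92. That range rests on 3 probe sets, so a mean above it can still be background. Adjusted p-values beside single genes are limma's. The deleted genes also had an exact two-sided permutation test over the 20 ordered splits of the arrays.

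Before the data were examined, 25 gene lists with 804 entries were fixed from general knowledge of Myc biology, stem cells, the inducer and other marrow cell types. Of these entries, 727 had a probe set of 1 gene, and the rest, such as Isg15, are not analysed here. Lists were tested with camera at a preset correlation of 0.01 on the representative probe sets, adjusted over the 25 lists, and with an estimated correlation as an alternative. The genes named were also fixed by rule: Myc, Mycn and Gzmb, the 10 largest rises and 10 largest falls among representative probe sets past the threshold with groups that do not overlap, passing over genes without a symbol, and the 3 members of each list with the smallest p. This gave 88 genes. Other members are given as examples of a list, or where a count of 5 or fewer named them, and were chosen after their values were seen.

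On simulated data of the same size, with 200 probe sets changed, the test recovered 32% of the probe sets changed by 1 on the log2 scale and 66% of those changed by 2. It made 3 false calls (2.97% of calls). The real comparison called 3146 probe sets, and the adjustment depends on how many change, so these shares need not hold for it. In the simulation of lists over 18193 genes, a list shifted by 0.5 was called, also with an estimated correlation, and 0 of 24 unchanged lists were called at the preset one. The simulated genes were drawn independently of each other, so this does not test the preset correlation. In the measured data the estimated correlations reached 0.219, for the granulocyte list.

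Alternatives were other between-array scalings, a filter on level, a trended robust prior, array weights, a replicate block, leaving out each array, leaving the deleted genes out of the lists (chosen after seeing the data), other thresholds, other probe set choices and other list tests. The alternative of adding 16 before a log2 transform was not run, because the values were already logged. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.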

Results

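Gene expression was measured in long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood formation for life. They were sorted as Lin-Sca1+CD150+CD48- cells from mice of 8 weeks on a mixed genetic background. In the double knockout (dKO) mice the floxed c-myc (Myc) and N-myc (Mycn) genes were open to the MxCre recombinase, whose promoter responds to interferon and is switched on by pI-pC, a synthetic double-stranded RNA. Control mice carried the same floxed genes without the recombinase and were also given pI-pC. Marrow was taken 3 days after the last of 2 daily doses. Each group had 3 arrays, and each array held RNA from its own pool of mice, 3 mice per dKO pool and 2 per control pool. The comparison asks which transcripts differ between stem cells with and without the pair of Myc genes shortly after deletion. Array medians lay between 5.90 and 5.97 on the log2 scale. Pearson correlations across probe sets were 0.974 to 0.981 within groups and 0.956 to 0.969 between groups. The first principal component held 48.2% of the variance and separated the groups. The Gapdh 3' minus 5' difference of the array controls, a sign of RNA quality, was 2.12 to 2.36 in control and 2.39 to 2.47 in dKO arrays. With 3 arrays per group, their number limits the precision.

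Both deleted genes fell in the dKO arrays. Myc, a transcription factor that drives growth and proliferation, dropped from 10.36 ± 0.23 to 7.43 ± 0.30 (SD, n = 3 arrays per group, log2 RMA values), a 7.63-fold decrease (log2 change -2.93 ± 0.20 SE, limma adjusted p = 0.00137). One Mycn probe set, 1417155_at, dropped from 10.81 ± 0.06 to 3.46 ± 0.32 (SD, n = 3 per group), a measured log2 change of -7.35 ± 0.18 (SE, limma adjusted p = 2.34e-05). That dKO level lay in the range of the negative control probe sets, 2.13 to 3.92, so the change is a lower bound, at least 119-fold against the highest of them. The brighter-on-average Mycn probe set, 1425922_a_at, fell by 1.61 ± 0.22 (SE, log2), or 3.05-fold (limma adjusted p = 0.00938). The remaining Mycn probe set, 1425923_at, was near 4 in both groups, at 4.40 and 4.32 (adjusted p = 0.858). The 3 Mycl probe sets, for the L-myc paralog, had log2 differences of -0.10, 0.00 and 0.09 and did not pass the test. The labels do not place the probe sets inside or outside the deleted segments, so the residual signals set no bound on deletion. The exact two-sided permutation p was 0.1 for Myc and for the Mycn probe sets 1417155_at and 1425922_a_at, the smallest that 3 arrays against 3 allow.

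Across the array, 3146 of 45037 probe sets (6.99%) passed a limma adjusted p of 0.05. Of these, 1608 were higher in dKO cells and 1538 lower. At least 2-fold changes were shown by 867 higher and 813 lower probe sets, and at least 8-fold changes by 45 higher and 6 lower. By 1 representative probe set per gene, 817 genes rose and 647 fell among 18193. The dKO and control values did not overlap at 27.4% of probe sets, where chance gives 10%, and all 3146 called probe sets were among them. With 1 array left out the count was 1665, 1561 or 1674 without control replicate 1, 2 or 3, and 1338, 1510 or 1551 without dKO replicate 1, 2 or 3.

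The largest rise among named genes was that of Gzmb, granzyme B, the serine protease of cytotoxic granules. Its level went from 5.45 ± 0.11 to 12.63 ± 0.15 (SD, n = 3 per group), a 144-fold increase (log2 change 7.17 ± 0.14 SE, limma adjusted p = 8.91e-06). Next came Ppbp, the precursor of a platelet chemokine (log2 change 5.67 ± 0.30 SE), and Gem, a small GTPase (5.04 ± 0.53). Csrp3, a LIM-domain protein of muscle, rose by 4.65 ± 0.24, the serotonin transporter Slc6a4 by 4.58 ± 0.27 and Bex6 by 4.53 ± 0.48. The other genes with the highest increases were the activation antigen Cd69 (4.04 ± 0.30), the complement receptor C3ar1 (4.02 ± 0.26), the SLAM-family receptor Cd244a (3.91 ± 0.18) and the immunoreceptor adaptor Clnk (3.77 ± 0.32). Among these 10 genes the adjusted p ranged up to 0.00444. Each was higher in 3 of 3 dKO arrays than in any control array, which the rule that named them required. The Bex6 controls, at 2.72, 4.79 and 4.30, had a mean of 3.94, near the top of the negative control range, so its exact change and rank rest on a level near background. The same holds for Slc6a4, with a control mean of 4.06. Of the Gem controls, at 6.17, 4.72 and 3.86, the last lay in that range. The control means of Gzmb, Ppbp, Cd69, C3ar1 and Clnk were above that range but under the lowest array median, 5.90. Background may therefore also enter their folds.

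Myc was among the 10 genes with the largest falls. Slc6a15, a neutral amino acid transporter, fell by 3.33 ± 0.23 (SE, log2), the carboxylesterase Ces2g by 3.26 ± 0.31 and Abca1, which exports cholesterol, by 3.18 ± 0.24. Neo1, the netrin receptor neogenin, had a log2 change of -2.70 ± 0.22, and 4930515G01Rik one of -2.71 ± 0.39. Aldh5a1 (-2.62 ± 0.24), Snhg14 (-2.61 ± 0.31), Far2 (-2.59 ± 0.32) and Exph5 (-2.54 ± 0.41) completed the group, with adjusted p up to 0.0156. The dKO means of Slc6a15 (3.54), Aldh5a1 (3.56), Snhg14 (3.57) and Exph5 (2.84) lay in the negative control range, so their folds are lower bounds, at least 7.77-, 4.80-, 4.79- and 2.76-fold against its highest value, and their ranks rest on such levels. Exph5 lost its call without dKO replicate 1 or dKO replicate 3, with an adjusted p of up to 0.0614.

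**Figure D1:**
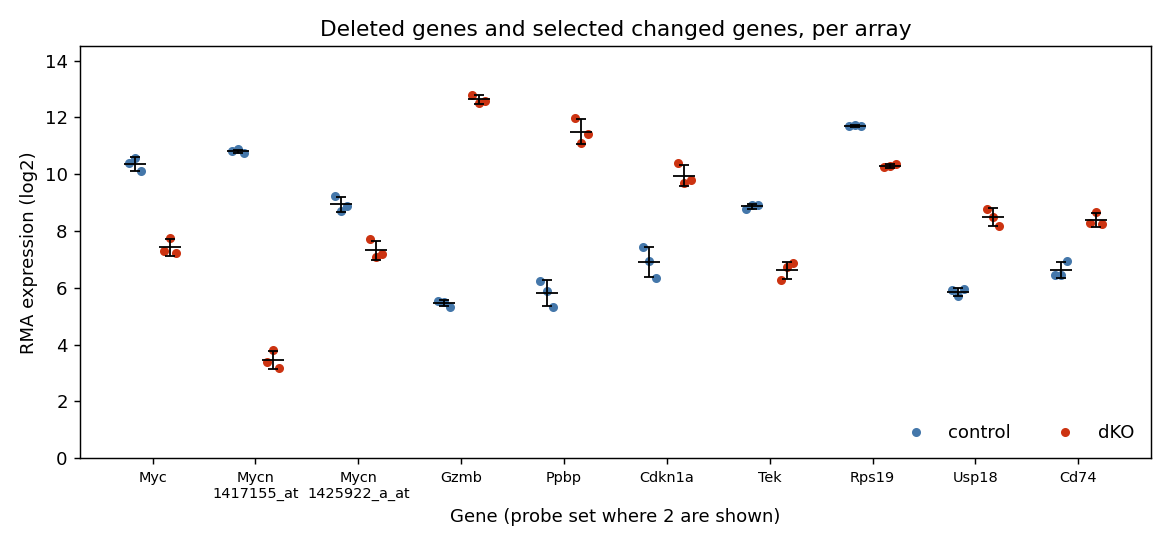
RMA expression (log2, vertical axis) of 9 genes in the 3 control arrays (blue) and 3 dKO arrays (red), with Mycn shown by 2 probe sets; points are arrays and the black bars are the mean ± SD. Control and dKO points do not overlap for any gene shown, with Gzmb at 5.45 against 12.63 and Mycn (1417155_at) at 10.81 against 3.46.

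Genes were then grouped into 25 lists fixed before the data were examined. By limma's camera test with a preset inter-gene correlation of 0.01, 11 lists were higher in dKO cells and 6 lower. None passed an adjusted p of 0.05 when camera estimated the correlation from the 6 arrays, where the lowest adjusted p was 0.0751, and 16 passed limma's fry test. At the preset correlation, splits of the arrays that mix the groups also called lists, up to 11. Such splits keep part of the group difference, so these counts are no measure of false calls.

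Ribosomal protein and ribosome biogenesis genes were lower in dKO cells. Of 32 measured cytosolic ribosomal protein genes, 19 fell, 0 rose and 13 did not pass, with a median log2 change of -0.77. Rps19 fell by 1.40 ± 0.12 (SE), Rplp0 by 1.29 ± 0.12 and Rps7 by 1.13 ± 0.13. The list's camera adjusted p was 5.07e-21, and adjusted p = 0.0842 with an estimated correlation. Of 49 ribosome biogenesis genes, which make and process ribosomal RNA, 12 fell and 0 rose (median -0.44, camera adjusted p = 3.38e-10, adjusted p = 0.1 with an estimated correlation). Dkc1, the pseudouridine synthase of small nucleolar particles, fell by 1.04 ± 0.14, the RNA cyclase-like Rcl1 by 1.06 ± 0.14 and the nucleolar chaperone Nolc1 by 0.95 ± 0.14. Adjusted over the list alone, 29 ribosomal protein genes and 23 ribosome biogenesis genes fell, and 1 biogenesis gene rose. Of the 29, Rps16 and Rpl37 were represented by probe sets with both group means in the negative control range. These probe sets do not measure the genes above background, so neither can be counted as a fall. With 1 array left out, between 8 (without dKO replicate 1) and 14 (without control replicate 3 or dKO replicate 2) ribosomal protein genes fell. Of the biogenesis genes, between 4 (without control replicate 1 or 2 or dKO replicate 1) and 8 (without dKO replicate 2) fell.

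Translation factors and tRNA synthetases did not pass the camera test as a list. Of 38, 6 fell and 1 rose, and adjusted over the list alone 7 fell and 2 rose. The initiation factor Eif4b fell by 1.23 ± 0.13 (SE, log2), and the elongation factors Eef2 and Eef1b2 fell by 1.05 ± 0.13 and 0.95 ± 0.13, while Aars, the alanyl-tRNA synthetase, rose by 1.09. The list median was -0.02 (camera adjusted p = 0.277), although fry, which asks whether the genes move 1 way on balance, gave an adjusted p of 0.0351. A second Eef2 probe set of low signal had a log2 difference of 0.62 (adjusted p = 0.106), and with the mean over both probe sets the Eef2 change was -0.21 (adjusted p = 0.393).

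The Myc network, the partners and antagonists of Myc proteins, had 5 of 12 genes lower and 0 higher (median -0.59, camera adjusted p = 5.37e-04, adjusted p = 0.1 with an estimated correlation). Myc and Mycn are the deleted genes, so their fall was set by the design; in a test added after the data were seen, the 10 other members had a median of -0.34 (camera adjusted p = 0.0236, adjusted p = 0.160 with an estimated correlation). Besides Myc and Mycn these were the Max-binding repressors Mxd4 (-0.92 ± 0.15 SE, log2), Mxi1 (-0.79) and Mga (-0.79). Adjusted over the list alone, 7 fell and 1 rose. Mxd4 lost its call without dKO replicate 1 or dKO replicate 2, with an adjusted p of up to 0.0548. Between 2 (without dKO replicate 1 or 2) and 4 members fell with 1 array left out.

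In nucleotide and polyamine synthesis, 2 of 31 genes fell, the purine enzyme Atic (-1.16 ± 0.23 SE, log2) and the folate enzyme Mthfd1 (-0.82 ± 0.16), and Rrm2, a ribonucleotide reductase subunit, rose by 1.28 ± 0.13. A total of 10 fell and 3 rose adjusted over the list alone. The list's camera adjusted p was 0.0459, against adjusted p = 0.294 with an estimated correlation. It reached 0.0802 and 0.116 without control replicates 1 and 2 and 0.0624 and 0.0504 without dKO replicates 1 and 2, and 0 members fell in these 4 settings. The camera adjusted p was 0.0181 after quantile normalization and 0.0319 with array weights, with 5 members lower in each. With the replicate block it was 0.061 and 0 members fell. Atic kept an adjusted p under 0.05 only without dKO replicate 3 and Mthfd1 only without control replicate 3, with values of up to 0.0921 and 0.0903 otherwise. Of 32 mitochondrial import and chaperone genes, 4 fell and 0 rose (median -0.22, camera adjusted p = 0.00104, adjusted p = 0.273 with an estimated correlation). They were the matrix protein C1qbp (-1.11 ± 0.14), the import factors Timm8a1 (-1.02 ± 0.17) and Timm9 (-0.84 ± 0.19), and the chaperonin Hspd1 (-0.57). The counts were 7 lower and 1 higher adjusted over the list alone. Timm9 lost its call with any 1 array left out (adjusted p up to 0.12) and Timm8a1 without control replicate 1 or 2 or dKO replicate 2 or 3 (up to 0.0598), and 1 to 2 members fell in those settings.

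Glycolysis and nutrient uptake genes changed in both directions, with 5 of 24 higher and 5 lower. Pfkp, a phosphofructokinase, rose by 1.58 ± 0.13 (SE, log2), the glucose transporter Slc2a3 by 1.47 ± 0.15 and pyruvate kinase Pkm by 1.09. The monocarboxylate transporter Slc16a1 fell by 1.63 ± 0.18, the kinase Pdk1 by 1.22 and the transferrin receptor Tfrc by 0.87. With p adjusted over the list alone, 8 rose and 8 fell. The list median was 0.12 and its mean -0.03 (camera adjusted p = 0.769), and with 1 array left out 2 to 3 genes rose and 2 to 3 fell.

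Of 21 cell cycle inhibitors and G1 cyclins, 7 rose and 1 fell (median 0.49, camera adjusted p = 5.37e-04, adjusted p = 0.0956 with an estimated correlation). Cdkn1a, which encodes the inhibitor p21, rose 8.27-fold (log2 change 3.05 ± 0.30 SE, limma adjusted p = 0.00383). The G1 cyclin Ccnd1 rose by 1.91 ± 0.17 and Ccnd3 by 1.72 ± 0.14, while the transcription factor Foxo3 fell by 0.71. A second Ccnd3 probe set went the other way (log2 change -2.21 ± 0.47, adjusted p = 0.0368), and the mean over its probe sets gave 0.14 (adjusted p = 0.699), so the Ccnd3 direction rests on the probe set used. Adjusted over the list alone, 12 rose and 3 fell, and 5 to 7 rose with 1 array left out.

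Of 40 DNA replication genes, 4 rose and 0 fell (median 0.39, camera adjusted p = 4.51e-06, adjusted p = 0.1 with an estimated correlation). They were the helicase subunits Mcm2 (1.11 ± 0.21 SE, log2) and Mcm5 (0.72 ± 0.14), the sliding clamp Pcna (0.60 ± 0.13) and the flap endonuclease Fen1 (0.80), and 12 rose and 0 fell adjusted over the list alone. The calls of Mcm5 and Pcna were lost with any 1 array left out (adjusted p up to 0.0891 and 0.102), and that of Mcm2 with any but control replicate 1 (up to 0.0839). In the leave-outs, 3 members rose without control replicate 1, 1 without control replicate 3, and 0 without control replicate 2 or any of the dKO replicates. With all arrays, 10 rose with each array centred on its median, 3 after quantile normalization and 0 with the replicate block. By their representative probe sets, none of 44 mitosis genes passed limma's test in either direction, adjusted over the whole array or over the list alone (median -0.02, camera adjusted p = 0.366). Without control replicate 3 the mitosis list was lower, with a median of -0.12 and a camera adjusted p of 0.0477. Cenpa, Hmmr and Cenph, which act at centromeres and the spindle, had the smallest p, with log2 differences of -0.64, -0.47 and -0.47 (adjusted p = 0.0604, 0.0939 and 0.102). Of 2 other Cenpa probe sets, 1 was lower past the threshold, by 1.13 (adjusted p = 0.0424). Mki67, a marker of cycling cells added after its value was seen, differed by -0.09 (adjusted p = 0.759).

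Interferon response genes were widely higher in dKO cells. Of 44 measured, 25 rose, 0 fell and 19 did not pass, and 36 were higher in every dKO array than in every control array. Usp18, which restrains interferon signalling, rose by 2.63 ± 0.19 (SE, log2), the nucleic acid sensor Zbp1 by 2.53 ± 0.16 and the immunity GTPase Iigp1 by 1.71 ± 0.13. Their adjusted p values were 0.00161, 0.00101 and 0.00187. The list median was 0.93 (camera adjusted p = 9.18e-22, adjusted p = 0.0751 with an estimated correlation), and 35 rose adjusted over the list alone. With 1 array left out, between 14 (without dKO replicate 2) and 19 (without control replicate 1) rose. Both groups had been given pI-pC, itself an inducer of interferon, and arrays from mice without it were not part of the comparison.

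Cytotoxic granule genes were higher, though not all of them. Of 14, 4 rose and 0 fell (median 0.87, camera adjusted p = 1.01e-04, adjusted p = 0.101 with an estimated correlation), and 7 rose adjusted over the list alone. Besides Gzmb, these were Gzmc (measured log2 change 3.22 ± 0.14 SE, adjusted p = 3.62e-04), Nkg7 (2.57 ± 0.22) and the granule proteoglycan Srgn (0.57 ± 0.13), whose call was lost with any 1 array left out (adjusted p up to 0.132). The control mean of Gzmc, 3.51, lay in the negative control range, so its rise is a lower bound, at least 7-fold. The pore-forming Prf1 differed by -0.12 (adjusted p = 0.751) and Gzma by 1.87, with dKO values from 6.02 to 8.91 (adjusted p = 0.295). With 1 array left out, 3 to 4 members rose.

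Neither list of lymphoid cell markers, which the sort should leave out, passed the camera test with all arrays. Of 27 T and NK cell genes, 2 rose and 1 fell, with the same counts adjusted over the list alone (median 0.18, camera adjusted p = 0.182). Thy1 rose by 1.25 ± 0.21 (SE, log2) and the receptor Klrk1 by 2.08 ± 0.42 (at least 4.03-fold, as its control mean of 3.85 lay in the negative control range), while Cd247, the zeta chain of the T cell receptor complex, fell by 0.77 ± 0.13. Cd247 lost its call with any 1 array left out, Thy1 without control replicate 2 or 3 or dKO replicate 2, and Klrk1 without control replicate 1 or 3 or dKO replicate 1 or 2, with adjusted p of up to 0.0632, 0.0605 and 0.101. Of its other probe sets, 1426396_at fell by 1.45 (adjusted p = 0.0213), 1420716_at differed by -0.29 (adjusted p = 0.681) and 1 near background by 0.25 (adjusted p = 0.516), and with the mean over its probe sets Cd247 changed by -0.57 (adjusted p = 0.0515). Without dKO replicate 3 the list was higher, with a camera adjusted p of 0.0141 and a median of 0.27, and Klrd1 was at 5.86, 5.83 and 4.05 in dKO replicates 1 to 3. Of 22 B and plasma cell genes, 1 rose, Xbp1, a transcription factor of the unfolded protein response and of plasma cells (log2 change 3.21 ± 0.34), and 2 rose adjusted over the list alone (camera adjusted p = 0.769). Cd22 differed by 0.85 and did not pass (adjusted p = 0.0532), and Blnk, named by the rule, was in the negative control range in both groups (means 3.84 and 3.22, adjusted p = 0.135).

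Of 26 monocyte, macrophage and dendritic cell genes, 9 rose and 0 fell (median 0.33, camera adjusted p = 1.80e-04, adjusted p = 0.160 with an estimated correlation). They included the integrin Itgax (log2 change 2.86 ± 0.22 SE), the Fc receptor chain Fcer1g (2.25 ± 0.17) and genes of class II antigen presentation, Cd74 (1.77 ± 0.20), H2-Aa (2.02), H2-Ab1 (1.17) and H2-Eb1 (1.35). Lyz2 and Ctss, abundant in macrophages, differed by -0.18 and 0.07 (adjusted p = 0.623 and 0.929). Adjusted over the list alone, 11 rose and 1 fell. Between 5 (without control replicate 1 or dKO replicate 1 or 2) and 7 (without control replicate 2 or dKO replicate 3) rose with 1 array left out. Of 20 granulocyte genes, 1 rose, Ms4a3 (1.17 ± 0.17), with the same count adjusted over the list alone, and the list had a median of -0.47 (camera adjusted p = 0.141). Ngp and Gfi1 differed by -0.60 and -1.59 (adjusted p = 0.0746 and 0.0975). Mpo, the peroxidase of granulocyte precursors, varied within groups, at 8.23, 10.58 and 8.58 in the controls and 5.74, 9.04 and 5.56 in dKO replicates 1 to 3 (adjusted p = 0.236). Without control replicate 3 or dKO replicate 2 the granulocyte list was lower, with camera adjusted p of 0.0477 and 0.0302 and medians of -0.30 and -0.51.

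Platelet and mast cell lists were higher, each led by a few genes. Of 21 megakaryocyte and platelet genes, 8 rose and 1 fell (median 0.38, camera adjusted p = 1.88e-04, adjusted p = 0.256 with an estimated correlation), and 9 rose and 2 fell adjusted over the list alone. After Ppbp, the adhesion receptor Selp rose by 3.48 ± 0.20 (SE, log2) and the tetraspanin Cd9 by 1.38 ± 0.16, whereas Vwf, von Willebrand factor, fell by 1.04. Gp9 and Gp1bb, subunits of the platelet receptor for that factor, differed by 0.20 and -0.23 (adjusted p = 0.456 and 0.407). With 1 array left out, between 4 (without control replicate 3 or dKO replicate 1 or 3) and 6 (without control replicate 1 or 2) rose. Of 14 mast cell and basophil genes, 3 rose and 0 fell, with the same counts adjusted over the list alone (median 0.57, camera adjusted p = 0.00159, adjusted p = 0.101 with an estimated correlation). They were Gzmb and Srgn, which the cytotoxic list also holds, and the IgE receptor subunit Fcer1a (1.93 ± 0.42). Fcer1a lost its call with any but control replicate 3 left out (adjusted p up to 0.122), and 1 to 2 members rose in the leave-outs.

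Few erythroid or stromal markers passed the test. Of 18 erythroid genes, 1 fell, the transcription factor Klf1 (log2 change -1.64 ± 0.26 SE), with the same count adjusted over the list alone, and the list did not pass (median -0.22, camera adjusted p = 0.0726). It was lower without control replicate 1 (0.0219, median -0.22) or dKO replicate 1 (0.0333, median -0.31). Gata1 and Epb42 differed by 0.66 and -0.32 (adjusted p = 0.145 and 0.196). Of 19 endothelial and stromal genes, 2 rose, the matrix glycoprotein Sparc (3.11 ± 0.37) and Pecam1 (1.19 ± 0.19), and 3 adjusted over the list alone (median 0.24, camera adjusted p = 0.0459, adjusted p = 0.256 with an estimated correlation). The collagen genes Col1a1 and Col1a2 were at 11.03 and 10.79 in dKO replicate 3, against 8.20 to 8.33 and 8.79 to 8.90 in the other dKO arrays (adjusted p = 0.0603 and 0.108). The stromal list's adjusted p was 0.0739, 0.0674 and 0.177 without control replicate 2, control replicate 3 and dKO replicate 1, and Pecam1 lost its call without dKO replicate 1 or 3 (up to 0.0554).

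Stem cell identity genes were lower on balance. Of 42, 9 fell and 3 rose (median -0.36, camera adjusted p = 0.00163, adjusted p = 0.191 with an estimated correlation), and 14 fell and 4 rose adjusted over the list alone. Tek, the angiopoietin receptor Tie2, fell by 2.25 ± 0.18 (SE, log2) and the adhesion molecule Esam by 1.37 ± 0.18, while the cytokine signalling inhibitor Socs2 rose by 1.82 ± 0.17 and Egr1 by 1.63 ± 0.23. Mycn, a deleted gene, and Vwf, counted in other lists too, were among those that fell, and without Mycn, also tested after the data were seen, the camera adjusted p was 0.00432 (adjusted p = 0.256 with an estimated correlation). Kit, the receptor for stem cell factor, fell by 0.87 ± 0.12 (adjusted p = 0.0101). Of the surface markers of the sort, Slamf1, which encodes CD150, differed by 0.08 (adjusted p = 0.855), and Cd48 rose by 1.16 ± 0.21 (adjusted p = 0.0214), both picked after their values were seen. With 1 array left out, between 5 (without control replicate 1, 2 or 3 or dKO replicate 1) and 8 (without dKO replicate 3) fell and 2 rose.

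Adhesion and homing genes were higher, with 15 of 37 up and 2 down (median 0.35, camera adjusted p = 2.54e-05, adjusted p = 0.0751 with an estimated correlation). Selp led, followed by the junctional molecule Jam2 (log2 change 2.81 ± 0.29 SE) and the integrin chains Itgb2 (1.74 ± 0.18) and Itgal (1.65). Esam and the integrin chain Itga4 (-0.84) fell. There were 16 rises and 3 falls adjusted over the list alone. Between 8 (without dKO replicate 1) and 11 (without control replicate 1 or 2) rose with 1 array left out.

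Of 37 apoptosis genes, 7 rose and 0 fell, with the same counts adjusted over the list alone (median 0.19, camera adjusted p = 0.0134, adjusted p = 0.256 with an estimated correlation). Those that rose included the survival genes Bcl2l1 (log2 change 1.88 ± 0.21 SE) and Bcl2 (1.17 ± 0.14) as well as the death-promoting Pmaip1 (2.12), Bak1 (0.71), Casp8 (0.76) and cytochrome c, Cycs (1.16 ± 0.18). Cycs lost its call without dKO replicate 1 or 2 (adjusted p up to 0.0583), and 2 to 4 members rose with 1 array left out, the fewest without dKO replicate 1 or 2. Of 30 p53 target genes, 4 rose and 2 fell (median 0.20, camera adjusted p = 0.0801), and 7 rose and 3 fell adjusted over the list alone. Cdkn1a, Ccnd1 and Pmaip1 rose, and Sesn1, a stress-induced regulator of growth signalling, fell by 1.05 ± 0.12. The p53 list was higher without control replicate 1 (camera adjusted p = 0.0226, median 0.33) or dKO replicate 3 (0.00612, median 0.35).

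Of 33 stress and immediate early genes, 6 rose and 0 fell, and 8 rose adjusted over the list alone (median 0.13, camera adjusted p = 0.0388, adjusted p = 0.510 with an estimated correlation). They included the transcription factor Egr1, the endoplasmic reticulum chaperone Hspa5 (log2 change 1.01 ± 0.15 SE) and Btg2 (1.05 ± 0.20). Fos and Jun of the same list differed by -0.78 and -0.42 and did not pass. Btg2 lost its call without control replicate 1 or 2 or dKO replicate 1 or 3 (adjusted p up to 0.0794). The list's adjusted p was 0.117, 0.0551 and 0.135 without control replicate 1, control replicate 2 and dKO replicate 1, and 2 to 4 members rose with 1 array left out.

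**Figure D2:**
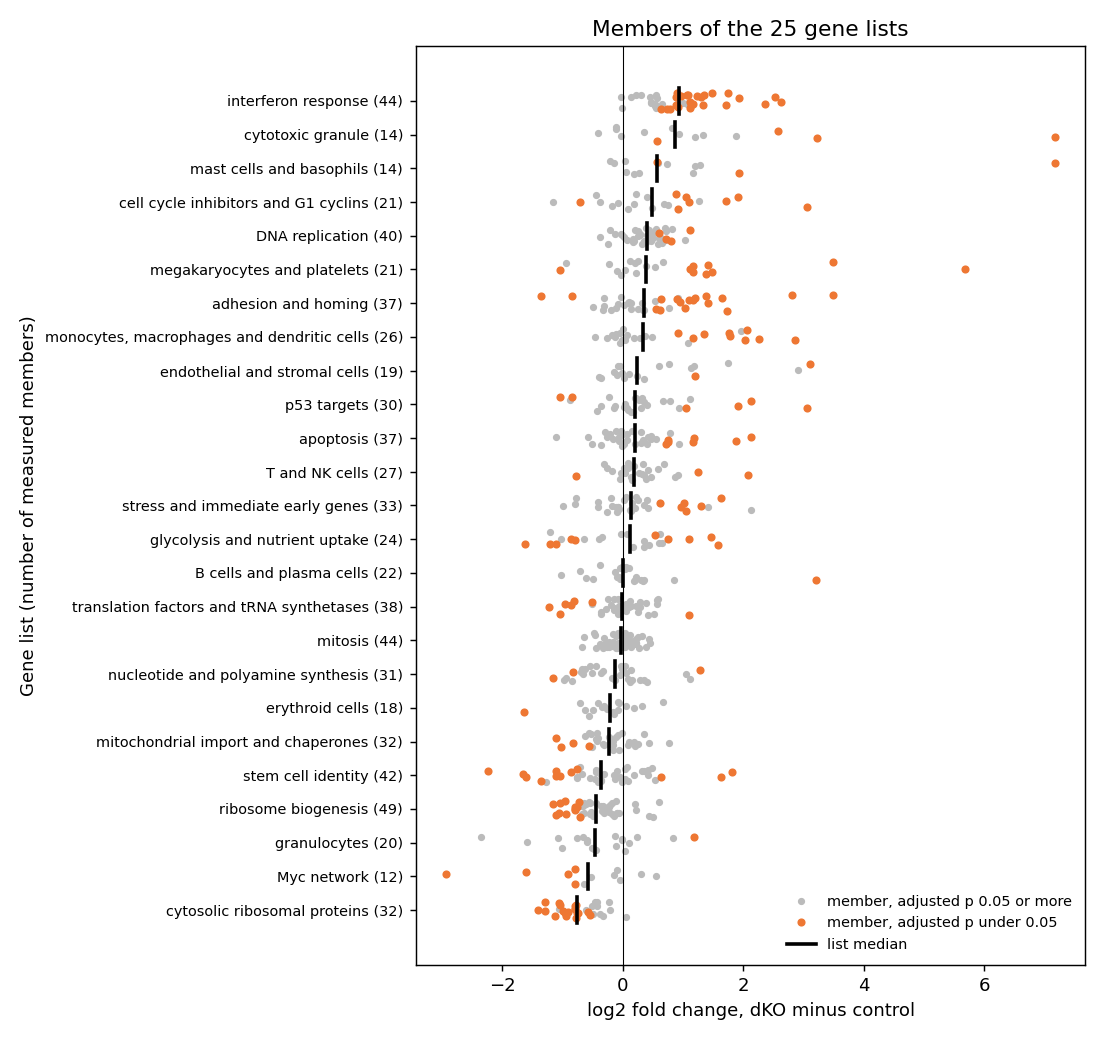
Log2 fold change, dKO minus control (horizontal axis), of each measured member of the 25 gene lists (vertical axis, member number in brackets), ordered by list median. Points are genes by their representative probe set, orange where the limma adjusted p was under 0.05 and grey otherwise, and black bars are list medians, from -0.77 for cytosolic ribosomal proteins to 0.93 for interferon response genes.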

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

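The array's own control probe sets were not part of the report's comparison, and 3 of them, which measure beta-actin, were higher in dKO than in control arrays by 0.85 (3' end), 0.82 (5' end) and 0.91 (middle) on the log2 scale, with limma adjusted p of 0.00959, 0.0119 and 0.00888. Each was higher in 3 of 3 dKO arrays, which the rule that flagged them required. Of the gene's own probe sets, 1436722_a_at rose by 0.78 (adjusted p = 0.0128), while the brighter 1419734_at differed by 0.41 and did not pass (adjusted p = 0.101). Of the 64 control probe sets, 2 others passed the test, both for the transferrin receptor, with log2 changes of -0.97 and -1.0 (adjusted p = 0.0489 and 0.0156). The Gapdh 3' minus 5' difference, a sign of RNA quality, was 2.12, 2.33 and 2.36 in control and 2.43, 2.39 and 2.47 in dKO replicates 1 to 3, so the groups did not overlap, while the beta-actin one was 0.10, 0.20 and 0.23 against 0.21, 0.20 and 0.21. With 3 arrays per group no test for a single outlying array was made.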

How the results depend on the processing

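Of the 3146 called probe sets, none changed sign under the between-array scalings that were run. The other settings could not have changed a sign. The filter on level, trended robust prior and replicate block leave the estimated change as it is. Array weights and leave-outs cannot reverse groups that do not overlap, as at all called probe sets. The count of called probe sets was 3030 after quantile normalization, 3178 with each array centred on its median (59.9% of calls higher, against 51.1%), 3977 among probe sets above the median level, 4053 with a trended robust prior, 3243 with array weights and 2567 without _x_at and _s_at probe sets. It was 5199 (2531 higher, 2668 lower) at an adjusted p of 0.1, 9765 (4692 and 5073) at an unadjusted p of 0.05, 1680 (867 and 813) with a 2-fold minimum and 1808 (1005 and 803) over 1 probe set per gene, each by construction of the threshold or of the set tested. Leaving out 1 array gave 1338 to 1674 calls, 708 to 893 higher and 630 to 812 lower, with fewer arrays in each fit. Values of same-numbered arrays did not deviate together (residual correlations -0.02, 0.00 and 0.01, none the highest for its number), so by this check the numbers do not pair the samples, although Xist was high in replicate 1 of both groups. With the replicate block 1530 probe sets passed (814 higher, 716 lower), 11 of 78 called named genes lost their calls, the nucleotide and polyamine list lost its call (camera adjusted p = 0.061) and the granulocyte and p53 lists gained one (camera adjusted p = 0.012 and 0.0267). Of the 78, 61 passed in each leave-out. Myc and both Mycn calls held under each alternative run.

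Of the 17 list calls (11 higher, 6 lower), 0 remained with an estimated correlation (0 higher, 0 lower). For the cell cycle inhibitor and adhesion lists the estimates, -0.028 and -0.0103, lay below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. For the other lists the cause was not tested. Counts under the other alternatives ran from 14 to 19. Calls for nucleotide synthesis, endothelial and stromal, and stress genes were the ones lost elsewhere. No named result changed sign past the threshold. Adding 16 before a log2 transform was not run. Signal over background limits dim genes: negative controls lay at 2.13 to 3.92, and Mycn (1417155_at) in dKO arrays was at 3.46.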

Other observations

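The tests of other cell types behind the Gzmb pattern and behind the interferon pattern were chosen after those results were seen. The 4 gene groups in the next paragraphs were also chosen after results on the same arrays were seen. Members not named as seen may still have been seen. A ranking by change that showed Socs2 (log2 change 1.82) would also show Pim2 (2.69) and Osm (1.97). The other members of that group changed less. The 4 groups are therefore no independent test of their themes. Their camera p-values were adjusted over 4 lists, against 25 for the fixed lists, so they cannot be ranked against those. The medians per dKO array and the lists without the deleted genes were also added after the data were seen. The remaining tests of explanations were set beforehand.

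Actin cytoskeleton genes were higher in dKO cells. Of 24 further genes, listed after the beta-actin probe sets, Tpm4, Enah and Gsn had been seen to be higher, 19 rose and 0 fell, with a median log2 change of 0.91 (camera adjusted p = 8.43e-18 over 4 such lists, adjusted p = 0.00251 with an estimated correlation). Cnn2, a calponin, rose by 1.62 ± 0.17 (SE), the filamin Flna by 1.48 ± 0.15, Tagln2 by 1.43 ± 0.15 and the actin gene Actg1 by 1.02 ± 0.12. Small nucleolar RNA host genes, which carry these RNAs in their introns, were lower: 9 of 11 fell and 0 rose (median -0.98, camera adjusted p = 2.82e-11, adjusted p = 0.0192 with an estimated correlation). Snhg4 fell by 1.73 ± 0.22, Snhg12 by 1.60 ± 0.25 and Gas5 by 0.98 ± 0.13. Adjusted over each list alone, 22 cytoskeleton genes rose and 11 host genes fell, of which Snhg18 (means 3.64 and 3.24) lay in the negative control range in both groups and cannot be counted as expressed.

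Cytokine signalling genes that depend on STAT factors, listed after Cish, Socs2 and Socs3 stood out, rose in 7 of 10 cases and fell in 0 (median 1.0, camera adjusted p = 1.63e-06, adjusted p = 0.0247 with an estimated correlation). The kinase gene Pim2 rose by 2.69 ± 0.20 (SE, log2), the cytokine Osm by 1.97 ± 0.21 and the receptor chain Il2ra by 1.13 ± 0.20, while Socs1 differed by 0.05 (adjusted p = 0.912). Of 16 genes that FoxO factors induce, listed after Klhl24, Tcp11l2 and Pdcd4, 6 fell and 1 rose (median -0.54, camera adjusted p = 3.74e-04, adjusted p = 0.0711 with an estimated correlation). Tsc22d3 fell by 1.64 ± 0.23 and Pik3ip1 by 1.56 ± 0.28, and Cited2 rose by 0.86 ± 0.15. Adjusted over each list alone, 7 STAT genes rose, and 8 FoxO genes fell and 2 rose.

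Gzmb rose with Gzmc, Nkg7, Itgax, Cd74 and Fcer1a, genes that other cell types also express. T or NK cells among the sorted cells would bring their abundant transcripts, but 10 of these had a median log2 change of 0.41, 0 of them past the threshold, and the 95% interval of Prf1 was -0.51 to 0.27, although Klrk1 rose by 2.08; the arrays differed, with medians over the 10 of 0.71, 0.77 and -0.13 in dKO replicates 1 to 3 and Gzma at 8.49, 8.91 and 6.02, so a small share of such cells in replicates 1 and 2 stays open, while Gzmb was at 12.79, 12.51 and 12.59. For macrophages or dendritic cells the median was 0.056 over 8 abundant transcripts, 0 past the threshold (Tyrobp differed by 1.07, adjusted p = 0.157), and 0.039 over the 5 with a control level under 7, but Itgax, Fcer1g, Cd74 and H2-Aa of the same list, not among the 8, rose by 2.86, 2.25, 1.77 and 2.02, and C1qb and Mrc1 by 1.78 and 2.05 (Mrc1 at least 4.11-fold, from a control mean in the negative control range), so these cells stay open. For mast cells or basophils the median over 6 was 0.50, again 0 past the threshold, with Cpa3 at 1.19 (adjusted p = 0.186) and Tpsb2 at 0.04. Expression of these genes by dKO stem cells themselves is a candidate explanation that stays open, as does a cell type outside these lists. The Lin- and CD48- gates of the sort are meant to leave out such lineages. The Cd48 transcript was itself higher in dKO cells, by 1.16 ± 0.21 (SE, log2, limma adjusted p = 0.0214), so the gates do not settle this.

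The interferon rise was not removed by scaling. Its list median of 0.93 (0.91 to 0.99 under the scalings tried) lay above all 10000 random lists of the same size and level, whose highest median was 0.44. It exceeded the highest median of the platelet, macrophage and lymphoid lists, 0.38, by 0.55. Members of those lists went both ways and some rose further, such as Itgax (2.86), Selp (3.48) and Ppbp (5.67). The medians therefore do not decide, and such cells stay open. The Lin- and CD48- gates of the sort are meant to leave them out, but the Cd48 transcript was itself higher in dKO cells, by 1.16 (log2). Whether the dKO mice respond differently to pI-pC cannot be told apart from the deletion, since 0 arrays came from mice without it, and the recombinase is present in the dKO group alone. Both may therefore contribute, besides the loss of the Myc genes.

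The ribosomal protein fall was compared with genes of like brightness. Its median of -0.77, at a mean level of 11.20, was below all 10000 random lists matched on level, the lowest of which had a median of -0.24. This argues against a bias shared by bright probe sets in general. Matching was by broad classes of level, so the brightest end was not matched closely. The highest values were 13.55 to 13.64 in dKO and 13.75 to 13.80 in control arrays. The list median was -0.66 after quantile normalization and -0.71 with each array centred on its median. When _x_at and _s_at probe sets, which can match several transcripts, were left out, 28 genes had a median of -0.78 and 18 of them fell. The fall therefore does not rest on these probe sets. They represented only 9 of the 32 genes, so the median could move little. Matches of the remaining probe sets to pseudogenes were not tested and stay open. Lower expression after Myc loss is a hypothesis, found and tested on the same arrays; cell composition, the response to pI-pC and the recombinase were not tested for this fall and stay open beside it.

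A test over splits of the arrays cannot reach a share under 0.05, because 6 arrays have 10 splits into 3 and 3. The real split called 3146 probe sets and 17 lists. The highest of the other splits called 0 probe sets by limma (1222 to 1762 at an unadjusted p under 0.05, against 9765) and 11 lists. Of the 10 splits 1, the real one, reached each real count. Each other split keeps part of the real difference and puts the rest into the spread within its groups. Its counts are therefore no rate of false calls.

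Xist, the transcript of the inactive X chromosome, was at 10.26 in control replicate 1 and 10.21 in dKO replicate 1 (probe set 1427262_at), the same replicate number in both groups, against 5.04 and 7.02 in control replicates 2 and 3 and 5.77 and 5.64 in dKO replicates 2 and 3. The Y-linked Eif2s3y (1417210_at) lay between 9.34 and 10.08 in all 6 arrays. The polyadenylated spike-in controls averaged 10.47 (log2) in control replicate 2, against 11.94 and 11.99 in the other controls and 11.21 to 11.33 in dKO arrays.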
